A study of Caenorhabditis elegans with 30 samples.

How the data were processed

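The deposited tables hold, for each library, the estimated counts per transcript that the authors obtained with kallisto, per the submitters' processing notes, which also name sleuth. The versions of kallisto and sleuth are not given in the sources used here, nor is the annotation release behind either transcript collection. Values were taken as estimated counts, summed per gene and rounded. Transcripts were matched to genes with the Ensembl 115 annotation of the WBcel235 build. Set 1 lists 37058 transcripts, of which 12 had no match, and 19988 genes. Set 2 lists 36172, of which 89 had no match, and 22027 genes, 2117 of them pseudogenes against 6 in set 1. The unmatched transcripts held at most 0.0182% of the counts of any library. No 2 libraries of the same group were duplicates (30 pairs compared, none across groups). The mark that separates the sets in the labels is not explained there, and the sets were modelled apart, except for the comparison of their N2 responses.

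Each set was fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with robust dispersions, TMM scaling, filterByExpr at a minimum count of 10 and a minimum total of 15, and 1 coefficient per group. P-values were adjusted within each of 13 comparisons by the Benjamini-Hochberg method, and adjusted p below 0.05 is written as rose, fell, higher or lower. Levels are CPM, counts over TMM-scaled library totals, and logarithms of levels used a prior count of 2. The 25 gene lists, written from general knowledge, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, in limma 3.58.1. Lists fixed from the other set held the genes that rose at least 2-fold in N2 of the other set. They were summarised by their medians, and the ceh-37 response over its list was also tested with fry, a self-contained list test in limma. Genes with 0 counts in a group were given a lower bound from a floor of 3 counts over the group, and those with 1 to 3 counts a 95% counting interval. DESeq2 1.42.0 served as the second tool, and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

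The comparisons, the lists, most alternatives and the rule for naming genes were set before the data were examined. That rule took, per comparison, up to 12 genes that rose and 8 that fell with the largest changes, 4 members of each list, the 12 smallest adjusted p of each difference between responses, and chil-27, chil-28, chil-18 and old-1 throughout. Genes shared by the strains of set 2, the lectin block and mitochondrial genes fall outside the rule and were chosen after their values were seen. The alternatives were DESeq2, its size factors in edgeR, no low-count filter, a transcript length offset, each library left out in turn, a replicate block, and only the compared groups in the fit. The median log2 change over all genes stayed within 0.0995 of 0 under every scaling tried. A self-test added changes of known size to 100 genes each in counts simulated for each comparison. The changed genes were not among those with few counts, and no library was made to stand apart. The rates that follow do not cover such genes or libraries. Changes of 1 on the log2 scale were found in 42% to 81% of genes and changes of 2 in 81% to 97%, and 1.43% to 7.10% of calls were false. Same-numbered libraries deviated together in every pair only between the N2 and clec-27 controls of set 2 (correlations of 0.171 to 0.465 over 3 pairs), a pairing that comes from the data and not from the labels, and that was recognised after the calls had been seen. Transcript-level tests were not run.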

Results

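The series measured messenger RNA in whole C. elegans nematodes that had, or had not, been exposed to an extract of Myzocytiopsis humicola, an oomycete that infects nematodes. Animals were grown to the L4 larval stage at 20 °C on E. coli OP50 and then given extract or water for 4 h. The 30 libraries form 10 groups of 3, which the labels call biological replicates, without saying whether they were grown on separate days, so p-values measure the spread between these samples. The labels mark 18 of the libraries apart from the other 12. Set 1 holds N2, the wild-type strain, and ceh-37(ok642), a mutant in a homeobox gene of the Otx family. Set 2 holds its own N2 animals and mutants in a pair of C-type lectin genes, clec-27(icb104) and clec-35(icb105). Estimated counts per library ranged from 18.6 M to 33.2 M in set 1 and from 18.2 M to 30.1 M in set 2. The sets were quantified against different transcript collections, so a mutant was compared only with the N2 animals of its own set. The series title describes the mutants as animals that do not respond to the oomycete, and the comparisons ask which part of the N2 response each mutant lacked.

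The mutated genes were read first in every library. Transcripts of ceh-37 (WBGene00000458, chromosome X, 14197372 to 14208000 in WBcel235) stood at 11.5 ± 0.573 CPM (SD, n = 3) in N2 controls of set 1 and 4.96 ± 0.600 in ceh-37 controls, a log2 difference of -1.22 (SE 0.13, edgeR adjusted p = 7.0e-05). With extract it had 367, 223 and 257 counts in N2 and 155, 196 and 191 in ceh-37 (6.02 ± 0.137 CPM). In set 2, ceh-37 lay between 10.7 ± 0.933 and 14.6 ± 1.46 CPM over the 6 groups. The gene clec-27 (WBGene00013607, chromosome V, 16854633 to 16856323) had 24, 15 and 16 counts in N2 controls of set 2 and 14, 6 and 2 in clec-27 controls, and with extract 9, 17 and 2 against 7, 0 and 6. This difference did not pass the test (log2 -1.22, SE 0.72, edgeR adjusted p = 0.279 among controls), so the counts do not tell whether the clec-27 libraries carry the mutation. Its neighbour clec-35 (WBGene00013608, chromosome V, 16852267 to 16854056) had 20, 28 and 18 counts in N2 controls and 8, 3 and 6 in clec-35 controls (log2 -2.08, SE 0.50, edgeR adjusted p = 0.0041), and with extract 10, 16 and 17 against 11, 8 and 5. Counts were summed over each gene and do not show which exons were read.

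In N2 animals of set 1 the extract switched on a small group of genes from near silence. The chitinase-like gene chil-18 (WBGene00011161) went from 0 counts in 3 control libraries to 3045 with extract, at least 781-fold, with an extract level of 35.9 ± 3.40 CPM (SD, n = 3). The chitinase-like chil-27, a widely used reporter of oomycete recognition, rose from 0.243 ± 0.272 to 11.3 ± 0.998 CPM (log2 5.63, SE 0.73, edgeR adjusted p = 0.0025). Transcripts of ddn-1 rose from 1.31 ± 0.300 to 258 ± 15.1 CPM (log2 7.62, SE 0.26, adjusted p = 8.7e-08), and the F-box gene fbxa-116 from 2 to 4244 counts, a ratio of 1633 with a 95% counting interval of 452 to 13485 (such intervals, and the at-least figures, cover counting error only). Of 22 chitinase-like genes, 9 rose and 13 did not pass, with 13 passing when adjusted over the list alone; chil-3 (log2 4.82) and chil-1 (log2 4.60) were among them. Of 32 pals genes, a family named for its ALS2CR12 signature and known from infection by microsporidia and virus, 16 rose (22 adjusted over the list alone), pals-29 at least 82.8-fold. The intracellular pathogen response, a set of genes induced by microsporidia and virus, had 6 of 12 members rise (9 over the list alone), including B0507.8 (log2 8.30) and skr-3, a Skp1-related ubiquitin ligase subunit (log2 0.68, SE 0.08). These 3 lists passed camera with an estimated correlation as well (adjusted p = 4.1e-05, 6.2e-05 and 0.00018). Of 217 F-box and MATH genes 5 rose (9 over the list alone; adjusted p = 0.032 with an estimated correlation). None of the 8 known regulators of the oomycete response passed over all genes, 3 rose when adjusted over the list alone, and the receptor kinase old-1 stood at log2 0.64 (SE 0.30, adjusted p = 1). In all, 90 genes rose and 4 fell of 15692 tested, among the latter the collagen col-150 (log2 -0.76) and the astacin protease nas-27 (log2 -1.03). Without N2 control replicate 2 the test called 204 genes. The chitinase-like, pals and F-box genes are multigene families whose reads can be shared between near copies, so the split between single members is uncertain.

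The N2 animals of set 2 showed a larger response around the same immune genes. Transcripts of chil-27 rose from 2 counts to 3120, a ratio of 1584 (95% counting interval 438 to 13082), and reached 42.8 ± 5.35 CPM (SD, n = 3), and chil-18 reached 130 ± 14.9 CPM from 0.120 ± 0.0920 (log2 9.99, SE 0.46, edgeR adjusted p = 2.3e-09). The related chil-28 went from 1 count to 665. The pals genes pals-28 and pals-5 had no counts in controls and rose at least 920-fold and at least 236-fold. Of 26 chitinase-like genes 17 rose and 2 fell (the same counts adjusted over the list alone), of 34 pals genes 25 rose and 1 fell (26 and 2 over the list alone), and of 15 intracellular pathogen response genes 14 rose (14 over the list alone). These lists kept their camera call with an estimated correlation (adjusted p = 0.00021, 0.00079 and 0.00038). Of 277 F-box and MATH genes 67 rose and 22 fell, and of the 8 oomycete regulators 4 rose (68 and 24, and 5, over the lists alone; adjusted p = 0.40 and 0.11 with an estimated correlation). Among infection effectors the invertebrate lysozyme ilys-3 rose (log2 4.80, SE 0.40), while lys-2 and irg-8, both known from bacterial infection of the gut, fell (log2 -1.01 and -0.96).

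Sperm, yolk protein and many cuticle collagen genes fell in the same N2 animals. Of 81 sperm protein genes 74 fell, of 6 yolk protein (vitellogenin) genes 6 fell and of 152 cuticle collagens 73 fell and 5 rose, with 74, 6 and 74 falling when adjusted over the list alone (adjusted p = 0.51, 0.62 and 0.51 with an estimated correlation). The yolk protein gene vit-2 went from 323 to 2.65 CPM on average (log2 -6.93, SE 1.38, edgeR adjusted p = 0.0039), and spe-9, needed by sperm to fertilise, fell by 1.78 on the log2 scale (SE 0.37). These genes moved with a score of developmental stage, the leading component of the sperm, yolk, oocyte, collagen, moulting and hedgehog-related genes. In set 2 the score was -1.46 in N2 control replicate 1, 0.41 and 0.70 in the other N2 controls, and -1.48 to -1.39 with extract, so 1 control stood with the treated animals. In set 1 all 6 N2 libraries lay between 0.56 and 0.72. The N2 response of set 2 comprised 1963 genes that rose and 2524 that fell of 16538 tested, and 535 that rose and 231 that fell were called when the score entered the model, so the balance turned. The count was 6047 without N2 control replicate 1, 2773 without control replicate 2, 1670 without control replicate 3, 2766 without extract replicate 1 and 2807 without extract replicate 2, and 1021 that rose and 566 that fell when the other strains were left out of the fit.

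**Figure D1:**
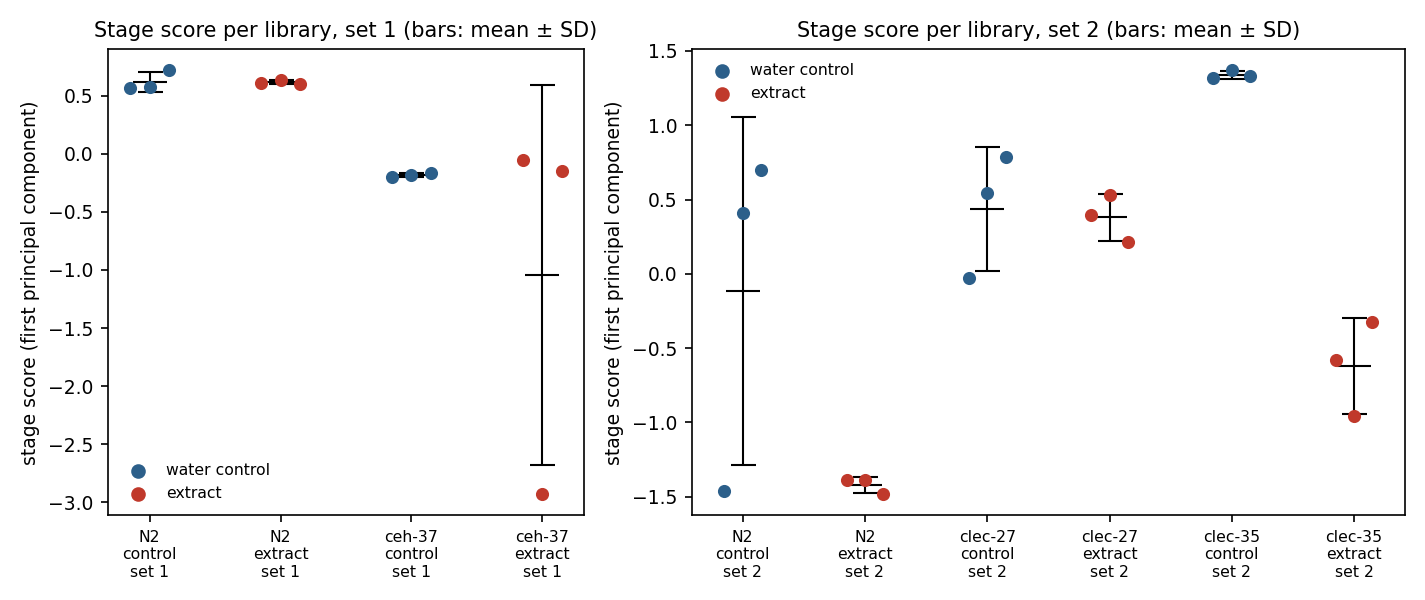
Stage score of each library (the leading principal component of log2 CPM over stage-related genes, no unit) by group, in set 1 (left) and set 2 (right), with bars for the mean ± SD of 3 libraries. ceh-37 extract replicate 2 lies at -2.93 in set 1, and N2 control replicate 1 of set 2 lies at -1.46, beside the N2 extract libraries of that set.

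A core of 88 genes rose in N2 of both sets. The mutants are compared below with these same N2 libraries, so the choice of the core favours lower values in the mutants. Set 1 had 89 and set 2 had 1828 rising genes among the 15395 tested in both, and independent lists of these lengths would share 10.6 (Fisher's exact p = 4.4e-81). Their median log2 change was 4.43 in set 1 and 6.16 in set 2, or 4.38 and 6.08 with genes at 0 in controls (13 and 9) placed at their bound. The core was induced more in set 2 at 15 genes and less at 1, with a median difference of 0.97, and ddn-1 rose by 1.04 log2 units more in set 2 (SE 0.22, edgeR adjusted p = 0.033). The intracellular pathogen response had 4 of 14 members more induced in set 2 (7 adjusted over the list alone; adjusted p = 0.074 with an estimated correlation). Over all genes the log2 changes of the sets correlated weakly (Pearson 0.420, Spearman 0.150, across genes, which are not independent replicates). Altogether 246 genes responded more positively and 140 more negatively in set 2, of 15801 tested, against 753 and 1418 by DESeq2. That count was 4200 without N2 control replicate 1 of set 2 and 189, 136 and 153 without its control replicate 2, extract replicate 1 and extract replicate 2, and 208, 125, 146 and 147 without control replicate 1 and extract replicates 1, 2 and 3 of set 1.

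**Figure D2:**
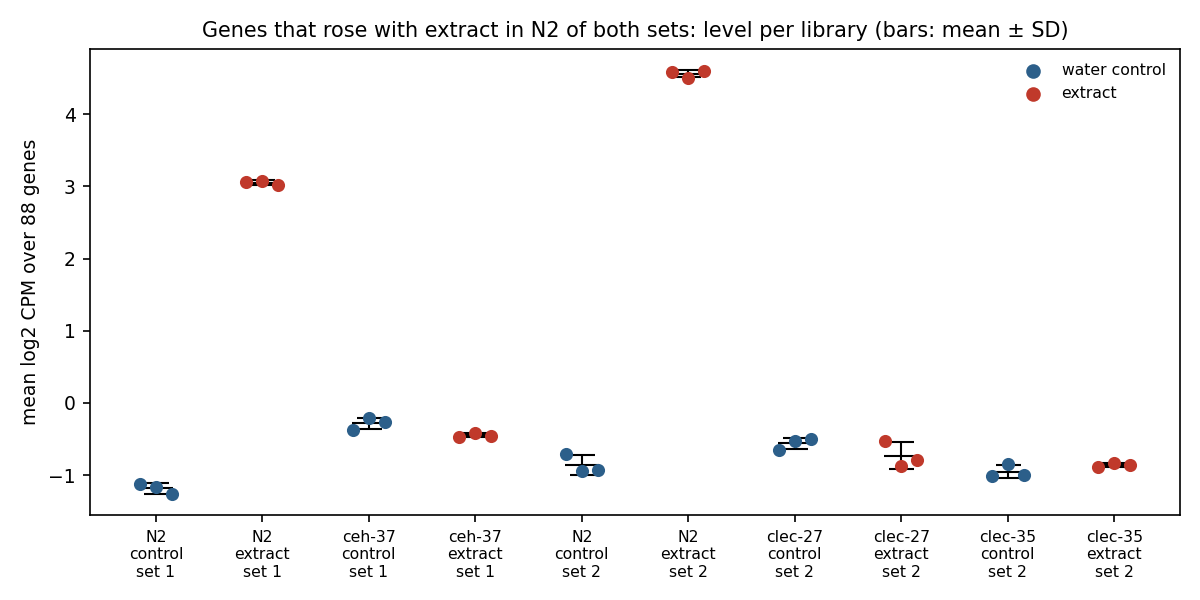
Mean log2 CPM over the 88 genes that rose in N2 of both sets, 1 point per library by group, with bars for the mean ± SD of 3 libraries. N2 extract libraries lie between 3.01 and 3.08 in set 1 and between 4.51 and 4.59 in set 2, and all 18 mutant libraries lie between -1.02 and -0.22.

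In ceh-37 animals the core did not rise with extract. Transcripts of chil-18 were at 15 counts in controls and 16 with extract, chil-27 at 21 and 14, and the median log2 change of the 88 core genes was -0.22, with 0 genes rising and 0 falling. In the test of the difference from N2, 51 of the 88 were lower in ceh-37 (80 by DESeq2), among them ddn-1 (log2 -8.49, SE 0.33, edgeR adjusted p = 3.6e-07), B0507.8 (log2 -9.40), pals-33 (log2 -6.30) and chil-1 (log2 -4.45). The difference for chil-27 missed the threshold (log2 -6.37, SE 1.24, adjusted p = 0.0837). By list, 4 of 22 chitinase-like, 12 of 32 pals and 5 of 12 intracellular pathogen response genes responded less than in N2, with 12, 20 and 7 adjusted over the list alone (adjusted p = 0.00033, 0.00033 and 0.00090 with an estimated correlation). Over all genes edgeR called 0 changes with extract in ceh-37 (smallest adjusted p = 0.0818), and DESeq2 called 0 rising and 3 falling. At an unadjusted edgeR p below 0.05 there were 501 genes, against 784.6 expected by chance. ceh-37 extract replicate 2 stood apart from the other 2 in stage score (-2.93 against -0.05 and -0.15). Without it edgeR called 1 gene. The difference from N2 comprised 1 gene more positive and 52 more negative in ceh-37, and 91 in all without N2 control replicate 2 and 109 by DESeq2. A list taken from the other set, the 705 genes that rose at least 2-fold in N2 of set 2, of which 592 were tested here, had a median log2 change of 0.21 in N2 and -0.12 in ceh-37 and a median difference of -0.39, with 87 rising in N2, 0 in ceh-37 by edgeR and 51 lower than in N2.

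In clec-27 animals the core was also not induced, while a different set of genes did change. The core had a median log2 change of -0.17, with 0 of 88 rising and 0 falling, and 72 were lower than in N2, where chil-27 (3 counts with extract, 4 without) passed the test of the difference (edgeR adjusted p = 0.0011), as did ddn-1 at log2 -9.66 and vsra-1 at -4.88 (SE 0.13, adjusted p = 4.8e-12). Of 26 chitinase-like genes 10 responded less than in N2, of 34 pals genes 17 and of 15 intracellular pathogen response genes 10, with 16, 26 and 13 adjusted over the list alone (1 chitinase-like gene responded more on that scale; adjusted p = 0.00012, 0.00021 and 0.00012 with an estimated correlation). The 85 tested genes of the list fixed from N2 of set 1 had a median of 6.31 in N2 and -0.17 in clec-27, a median difference of -6.54, and 85 of them rose in N2 and 0 in clec-27 by edgeR. The extract did raise the lactamase-like gene lact-6 from 0.155 ± 0.0687 to 20.4 ± 2.37 CPM (log2 7.02, SE 0.34, adjusted p = 2.1e-08), the thaumatin-like gene thn-1 (log2 4.58, SE 0.54), the lectin clec-70 (log2 4.15) and the glucuronosyltransferase ugt-15 (log2 4.10), and lowered the nuclear receptor nhr-8 (from 39.4 ± 1.87 to 13.9 ± 1.17 CPM, adjusted p = 6.0e-06) and the scavenger receptor scav-5 (log2 -1.60). Of 79 cytosolic ribosomal protein genes 0 passed over all genes and 56 rose when adjusted over the list alone, and of 10 heat shock genes 0 and 7 (adjusted p = 0.60 and 0.18 with an estimated correlation). In all 139 genes were called in clec-27 of 16538 tested, 72 rising and 67 falling. The count was 55 without control replicate 2, 223 (91 rising and 132 falling) without control replicate 3, 82, 86 and 63 without extract replicates 1, 2 and 3, 397 by DESeq2, 302 with the stage score in the model and 45 when the other strains were left out. The difference from N2 comprised 55 genes more positive and 261 more negative in clec-27, against 1273 and 624 by DESeq2. That count was 3344 without N2 control replicate 1, 190 and 175 without N2 control replicates 2 and 3, 166 and 185 without N2 extract replicates 1 and 2, and 173 and 190 without clec-27 control replicate 2 and extract replicate 2.

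In clec-35 animals most of the core was likewise missing, inside a much wider change. Transcripts of chil-27 went from 14 counts to 3 (ratio 0.239, 95% counting interval 0.044 to 0.856), chil-18 from 2 to 7 without passing the test (adjusted p = 0.193), and the median log2 change of the core was 0, with 16 genes rising and 13 falling. Of the 88 core genes 77 were lower than in N2, among them T20D4.7 (log2 -7.31), ddn-1 (log2 -7.96, SE 0.31, edgeR adjusted p = 8.3e-10) and chil-27 (adjusted p = 3.0e-06). Those not called lower were not all retained. The genes thn-4, pals-28, F15H10.12, fbxa-28 and C32B5.13 had a log2 change of 0 in clec-35. Their differences from N2, from -12.8 to -8.07, did not pass. The list fixed from set 1 differed from N2 by a median of -6.45. The core genes that rose in clec-35 included some with changes near those of N2, picked after their values were seen. They were srlf-34 (log2 3.56, N2 3.04, adjusted p of the difference 0.28), ins-5 (1.42, N2 1.32) and Y50D4B.6 (1.65, N2 1.72), and the rise of ins-5 was lost with the stage score in the model. Others rose much less than in N2, as ddn-1 (log2 0.76, SE 0.23, adjusted p = 0.0098) and B0507.8 (log2 1.49), and the receptor kinase old-1 rose (log2 1.22, SE 0.28, adjusted p = 0.0020). Of 26 chitinase-like genes 13 responded less than in N2, of 34 pals genes 20 and 1 more, and of 15 intracellular pathogen response genes 11, with 13, 22 (and 1 more) and 13 adjusted over the list alone (adjusted p = 0.0030, 0.0061 and 0.0030 with an estimated correlation). The number of core genes that rose was 10 without clec-35 control replicate 3 and 5 with the stage score in the model, where Y50D4B.6, ddn-1 and B0507.8 were no longer called.

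Oocyte, sperm and yolk protein transcripts fell with extract in the same clec-35 animals. All 18 oocyte and early embryo genes fell, as did 77 of 81 sperm protein genes and 6 of 6 yolk protein genes, while 68 of 79 cytosolic ribosomal protein genes, 12 of 17 pan-neuronal and 11 of 17 moulting genes rose (18, 78, 6, 72, 12 and 11 adjusted over the list alone; adjusted p = 0.61 with an estimated correlation for the oocyte, sperm, yolk, neuronal and moulting lists and 0.62 for the ribosomal list). Among the oocyte genes spn-4 fell by 2.19 on the log2 scale (edgeR adjusted p = 3.0e-05) and among the gut pathogen response genes, of which 2 rose and 13 fell (the same over the list alone; adjusted p = 0.61 with an estimated correlation), irg-2 fell by 3.13. The stage score moved with these lists, from between 1.32 and 1.37 in clec-35 controls to between -0.96 and -0.32 with extract. In all 9468 genes were called, 4991 rising and 4477 falling by edgeR and 4475 and 4931 by DESeq2, and 1445 calls were left with the score in the model. The response differed from that of N2 at 4228 genes and from that of clec-27 at 6247 (461 with the stage score, 3959 without clec-27 control replicate 1). In these comparisons the balance of upward and downward calls turned with the processing, so no direction is given for the differences as a whole.

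A smaller response was common to the 3 strains of set 2. It comprised 51 genes that rose and 23 that fell in N2, clec-27 and clec-35, where independent lists would share 2.58 and 2.77. That 0 of the 51 belonged to the core follows from the core genes, none of which rose in clec-27. For the same reason none of the 51 could be called as rising in N2 of set 1. The gene lact-6 rose by 7.59, 7.02 and 6.56 log2 units in N2, clec-27 and clec-35, ilys-3 by 4.80, 2.06 and 4.32, thn-2 by 4.20, 3.20 and 2.19, and the fatty acid desaturase fat-3 by 1.04, 0.85 and 1.39, while scav-5 changed by -1.59, -1.60 and -0.99. None of these genes was called in N2 or ceh-37 of set 1 by edgeR (50 and 23 tested, N2 medians 0.03 and -0.02), and 33 of the 51 and 19 of the 23 differed between the N2 animals of the sets, lact-6 by 7.75 (edgeR adjusted p = 2.6e-05). Without clec-27 control replicate 2 there were 31 and 11 genes, and without clec-27 extract replicates 1, 2 and 3 the falling genes numbered 12, 12 and 10. DESeq2 found 77 and 35. With only the compared groups in the fit the numbers were lower than in any of these fits.

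**Figure D3:**
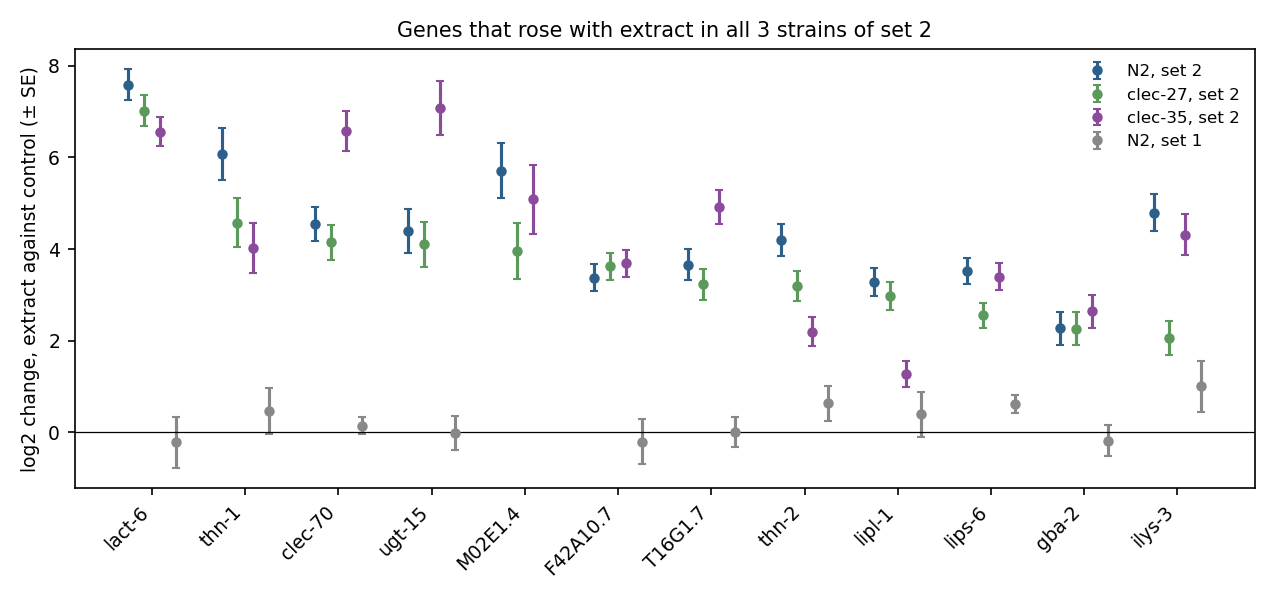
Log2 change with extract (± SE) of 12 genes that rose in all 3 strains of set 2, in N2, clec-27 and clec-35 of set 2 and, where measured, in N2 of set 1. lact-6 rose by 6.56 to 7.59 in the strains of set 2 and stood at -0.22 in N2 of set 1.

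Before any treatment ceh-37 animals already differed from N2 at many genes, and none of the lists given below passed camera with an estimated correlation. The intestinal lysozyme lys-7 stood at 0.576 ± 0.0758 CPM against 58.6 ± 9.24 in N2 (SD, n = 3; log2 -6.67, SE 0.27, edgeR adjusted p = 1.8e-08) and the fatty acid desaturase fat-7 at 30.3 ± 3.87 against 570 ± 69.96 (log2 -4.23), while its paralog fat-6 was higher (log2 1.79). The pathogen response genes irg-5 (log2 3.19, SE 0.13), clec-60 (log2 4.30) and irg-4 (log2 1.58) were higher. Of 17 intestinal pathogen response genes 9 were higher and 2 lower, of 146 C-type lectins 31 and 41, and of 32 pals genes 11 and 1, with 13 and 2, 32 and 46, and 16 and 2 adjusted over the list alone (adjusted p = 0.34, 0.35 and 0.34 with an estimated correlation). Of 17 moulting genes 10 were higher and 1 lower (12 and 1 over the list alone; adjusted p = 0.34 with an estimated correlation), with noah-1 up by log2 3.60 (adjusted p = 8.9e-09) and the furrow collagen dpy-7 by 3.40. The stage score of ceh-37 controls, -0.20 to -0.17, lay below that of N2. Of the core genes 29 were higher and 3 lower in untreated ceh-37 animals than in N2 controls, with a median of log2 1.07, B0507.8 by 2.34 and ddn-1 by 1.83. In all 2296 genes were higher and 1041 lower of 15692 tested. The count was 2150, 2130 and 2177 without ceh-37 control replicates 1, 2 and 3. The balance turned, to 2449 higher and 2784 lower, when the extract groups were left out. Genes on chromosome X, where ceh-37 lies, made up 18.7% of the called genes and 13.1% of the others (Fisher's exact p = 2.1e-15), and 16.52% and 11.71% without genes within 1 Mb of it (p = 1.0e-12). Of the 286 genes within 1 Mb 87 were called, or 30.4%, against 21.1% of the others (Fisher's exact p = 0.00025, a test added after the counts were seen). Neighbouring genes are not independent, so these Fisher p-values may be too small.

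A block of C-type lectin genes on chromosome V, which holds clec-27 and clec-35, was nearly silent in ceh-37 animals. The 13 lectin genes between 16839121 and 16869840 had 1654 counts in the 6 N2 libraries of set 1 and 10 in the 6 ceh-37 libraries, or 11.2 ± 0.900 against 0.0572 ± 0.0688 CPM (SD, n = 6), a 196-fold difference (exact permutation test, two-sided p = 0.0022, the smallest that the 924 splits allow; adjusted p = 0.0108). Of these genes 10 had 0 counts in all 6 ceh-37 libraries, and clec-26 went from 490 counts to 2 (282-fold lower, 95% counting interval 77.5 to 2332) and clec-31 from 193 to 0, at least 73.95-fold. The genes clec-27 and clec-35 had 41 and 33 counts in N2 and 0 in ceh-37, at least 15.7-fold and 12.65-fold lower (exact permutation p = 0.0022 and 0.0152, two-sided, adjusted 0.0043 and 0.0152). On one side the flanking gene tni-3 differed 1.02-fold over 6 libraries each. Over the same libraries phy-3, next to the block, went from 1187 counts to 752 (1.81-fold lower, 95% counting interval 1.65 to 1.99). Among controls phy-3 did not pass (log2 -0.59, SE 0.50, edgeR adjusted p = 0.40). On the other side the edge of the loss is not resolved. The nearest gene there, thn-4, belongs to the core and had no counts in N2 controls. It went from 217 counts in N2 to 0 in ceh-37. In set 2 it had 293 counts in N2 and 0 in clec-27 and clec-35, where the block was expressed. The next gene, srw-23, had 47 and 21 counts in N2 and ceh-37 over both treatments. Among controls it stood higher in ceh-37 without passing (log2 4.29, SE 1.72, edgeR adjusted p = 0.107). It had 92 counts in N2 of set 2 against 2 in clec-27 and 1 in clec-35. The block was chosen after its values were seen. In N2 it stood at 11.02 ± 1.09 CPM in controls and 11.40 ± 0.852 with extract in set 1, and at 18.36 ± 0.820 and 17.18 ± 1.16 in set 2 (n = 3). Here 3 libraries against 3 are too few for a test to pass (exact permutation p = 0.70 and 0.20, smallest possible 0.1). In set 2 it stood at 17.8 ± 1.11 CPM in N2, 14.9 ± 3.49 in clec-27 and 15.6 ± 3.53 in clec-35 (n = 6, control and extract together; exact permutation p = 0.0823 and 0.180 against N2). Within treatments some groups did not overlap. All clec-35 controls (12.46 ± 0.510 CPM, SD, n = 3) lay below all N2 controls and stood at 18.84 ± 0.638 with extract, and all clec-27 extract libraries (12.64 ± 1.84) lay below all N2 extract libraries. With 3 libraries against 3, chance separates 10% of such comparisons. Lectins elsewhere went both ways in ceh-37. Of 138 tested outside the block 33 were lower and 31 higher than in N2, 4 were at least 8-fold higher and 17 at least 8-fold lower, the latter 12.32% of them against 0.592% of other genes (Fisher's exact p = 2.3e-16). These 17 lie on 6 chromosomes and include clec-165 (549 counts to 0 over 6 libraries each), clec-7 (689 to 0) and clec-160 (log2 -3.99, SE 0.18). Several are neighbours, as clec-165, clec-166 and clec-167 on chromosome IV and clec-94, clec-95 and clec-96 on chromosome I. Such genes are not independent, so the Fisher p-value is too small. Reads may be shared among lectin paralogs, so single members are uncertain.

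**Figure D4:**
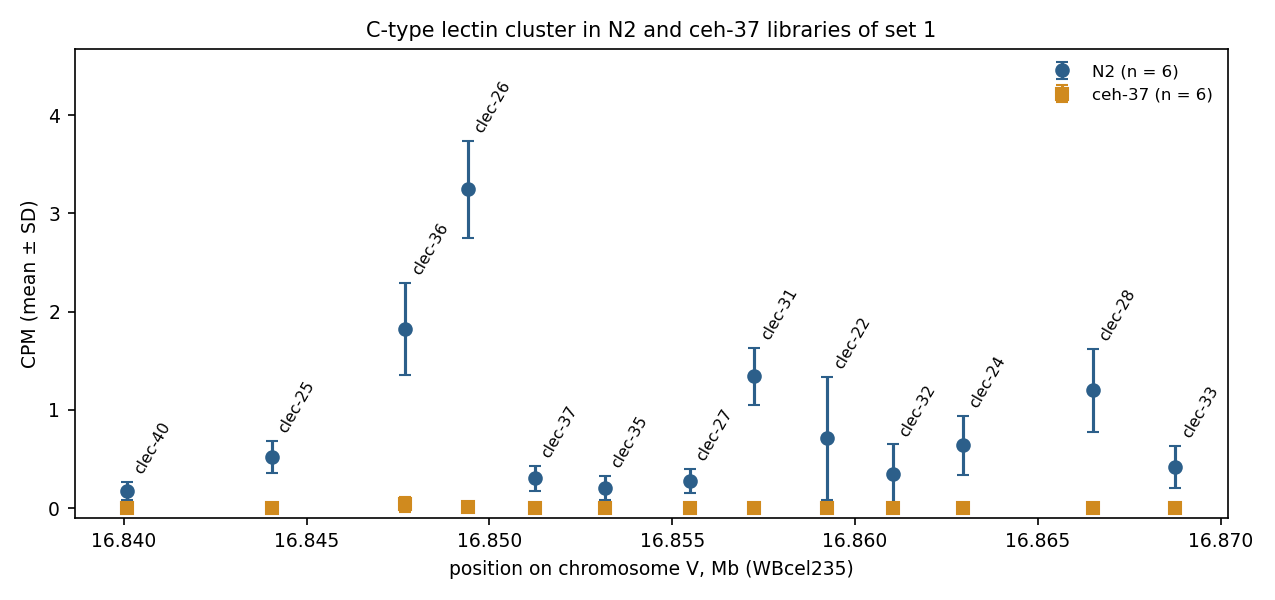
CPM (mean ± SD) of 13 C-type lectin genes against their position on chromosome V (WBcel235), in 6 N2 and 6 ceh-37 libraries of set 1. clec-26 is the most abundant in N2, with 490 counts over 6 libraries against 2 in ceh-37, and 10 of the 13 genes have 0 counts in ceh-37.

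Some genes differed by large factors between untreated clec-27 animals and N2. The chitinase-like gene chil-26 (WBGene00011847, chromosome II, 9475055 to 9476295) had 1126 counts against 6 in N2 (log2 7.45, SE 0.61, edgeR adjusted p = 6.6e-05), while its neighbour chil-27 (9477867 to 9479696) had 4 and 2 counts. The chemoreceptor gene str-46 had 3 counts against 204 (ratio 0.0148, 95% counting interval 0.0030 to 0.0439), and the X-linked genes F41G4.7 and F41G4.5 had none, at least 31.4-fold and 25.5-fold lower. Of 18 oocyte genes 3 were higher (18 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation) and of 68 hedgehog-related genes 10 were lower (15, with 1 higher, over the list alone; adjusted p = 0.59 with an estimated correlation). In all 730 genes differed of 16538 tested, with no stable balance of direction, against 1665 by DESeq2, 1531 with the stage score and 5 when only these 2 groups were fitted. The count was 320, 117 and 1199 without N2 control replicates 1, 2 and 3, and 3286 and 91 without clec-27 control replicates 1 and 3 (56 higher and 48 lower without its replicate 2).

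Untreated clec-35 animals carried more oocyte, sperm, yolk protein and gut pathogen response transcripts than N2. All 18 oocyte genes and 6 yolk protein genes and 52 of 81 sperm protein genes were higher, and 11 of 16 intestinal pathogen response genes were higher and 1 lower, among them irg-1 (log2 4.24, SE 0.64, edgeR adjusted p = 0.00024) and irg-2 (log2 3.26). Of 17 moulting genes 12 were lower and 1 higher, and of 36 lysozyme and saposin-like genes 17 were lower, with spp-25 at log2 -2.25 and lys-4 at -1.07. Adjusted over the list alone 18 oocyte, 6 yolk protein, 57 sperm protein and 11 pathogen response genes were higher. In the same way 13 moulting and 17 lysozyme genes were lower. Camera with an estimated correlation gave adjusted p = 0.52 for each of these lists. The chemoreceptor str-46 was again low, with 4 counts against 204 (log2 -5.60, SE 0.55, adjusted p = 3.0e-05), while chil-26 had 14 counts in clec-35 controls. In all 7640 genes differed, 3705 higher and 3935 lower by edgeR and 4230 and 3629 by DESeq2, and 3209 calls were left with the stage score. That score was 1.32 to 1.37 in clec-35 controls, and N2 control replicate 1, at -1.46, stood apart from the other N2 controls (0.41 and 0.70). Mitochondrial transcripts made up 0.338 ± 0.153% of the counts in clec-35 controls and 1.35 ± 0.125% in N2 controls (SD, n = 3). The clec-27 and clec-35 controls shared 276 higher and 276 lower genes, where independent lists would share 83.1 and 85.4, with 19 called in opposite directions. Both comparisons use the same 3 N2 libraries. The covariance of their log2 differences was 0.509, against 0.0621 on average in 20 simulated unchanged pairs, where 0 genes were called in both. The simulation drew every library from the mean of the N2 controls, without the stage difference of N2 control replicate 1. It therefore does not decide whether part of the excess comes from the shared controls. Genes on chromosome V, which holds both lectin genes, made up 22.3% of the calls and 20.9% of other genes in clec-27 (Fisher's exact p = 0.38; 19.5% and 19.8% without genes within 1 Mb). In clec-35 the shares were 19.86% and 21.99% (Fisher's exact p = 8.1e-04). Genes within 1 Mb were tested apart after the calls were seen. In clec-27 26 of these 260 genes were called, against 4.32% of the others (Fisher's exact p = 9.6e-05). In clec-35 it was 102 of 260, or 39.2%, against 46.3% of the others (Fisher's exact p = 0.024). Here too neighbouring genes are not independent, so the Fisher p-values for position may be too small.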

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

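Every test of an explanation and every regrouping of libraries in this part was chosen only after the result was seen. The results below stand out because the effect of the extract differed between groups in a test of the difference itself. No test for single far libraries was applied to groups of 3, and the libraries described as standing apart were noticed in their values.

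The response of ceh-37 differed from that of N2 at 53 genes, that of clec-27 at 316, that of clec-35 at 4228, clec-35 from clec-27 at 6247, and N2 of set 2 from N2 of set 1 at 386. Of the 88 core genes 51 were lower in ceh-37, 72 in clec-27 and 77 in clec-35. The core was chosen for its rise in the same N2 libraries, which favours lower values in the mutants. Core genes not called lower were not thereby retained. In each mutant thn-4 had a log2 change of 0, and its differences from N2 (-9.12, -9.60 and -9.60) did not pass. Lists fixed from the other set, chosen without the libraries tested, differed by medians of -0.39, -6.54 and -6.45. These medians depend on the list. With the list from N2 of the mutant's own set, chosen on the same libraries, they were -4.53, -1.39 and -1.40, so they do not rank the mutants. Median log2 differences from N2 were -2.23 for chitinase-like, -1.27 for intracellular pathogen response and -3.05 for pals genes in ceh-37. In clec-27 they were -2.10, -2.57 and -4.68, and in clec-35 they were -1.84, -1.75 and -5.12. Leaving out single libraries moved several of these counts. The ceh-37 count was 91 without N2 control replicate 2, and the clec-35 against clec-27 count 3959 without clec-27 control replicate 1. The clec-27 count was 3344, 190 and 175 without N2 control replicates 1, 2 and 3, 166 and 185 without N2 extract replicates 1 and 2, and 173 and 190 without clec-27 control replicate 2 and extract replicate 2. The count between sets was 4200, 189, 136 and 153 without control replicates 1 and 2 and extract replicates 1 and 2 of set 2, and 208, 125, 146 and 147 without control replicate 1 and extract replicates 1, 2 and 3 of set 1.

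Control and extract labels were regrouped within strains 30 times, the real labels included. As many calls as the real labels gave came from 1 regrouping for ceh-37 against N2 (53, highest other 50), 7 for clec-27 (316, highest other 2297), 2 for clec-35 (4228, highest other 4771), 3 between the lectin mutants (6247, highest other 8113) and 3 between the sets (386, highest other 532). Except for clec-27, every other regrouping with any calls kept or exchanged the whole of one strain or set, which leaves its effect of the extract in place, and those that mixed control and extract in both gave no calls by edgeR. Such regroupings are no measure of chance, and nothing is concluded from them. For clec-27 against N2, regroupings that mixed both strains gave up to 2297 calls, several times the real 316. The source of these calls was not tested, and chance cannot be excluded for that count.

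The first pattern is the loss of most of the core response in the mutants. With the stage score in the model at least 63 of the 88 genes were lower than in N2 in each mutant. This does not decide on developmental stage as a cause. In set 1 the score varied within groups mainly through ceh-37 extract replicate 2 (-2.93). In set 2 it did not separate stage from treatment in N2 and clec-35, as described below. The N2 control and extract libraries of set 1 all scored between 0.56 and 0.72. A difference in this score therefore does not account for the rise of the core in N2 there. A complete failure of exposure in the lectin mutants is argued against by the 51 genes that rose in all 3 strains of set 2, where independent lists would share 2.58, with lact-6 up by 7.59, 7.02 and 6.56 log2 units in N2, clec-27 and clec-35. Their median log2 change in N2 of set 1 was 0.03, so they do not show that the part of the extract which induced the core acted on these mutants, and another difference between the control and extract libraries of set 2 stays open. The verdict depends on its rule, because a stricter one, tried after these values were known and dropped, also asked that the genes respond in N2 of set 1 and would have left the question undecided. For ceh-37 no shared response was found (501 genes at an unadjusted p below 0.05 by edgeR, against 784.6 expected by chance). Extract replicate 2 stood apart at a stage score of -2.93, so a failed exposure of these libraries and a missing response cannot be told apart. A role of the mutated genes in recognising the oomycete is a candidate explanation that the design names, and it rests on 1 strain per gene.

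The second pattern is the near silence of the lectin block in ceh-37. Depth is argued against, as ceh-37 libraries were 1.14 times as deep as N2. The block stood at 10.5 CPM or more in all 18 libraries of set 2, whose stage scores ran from -1.48 to 1.37. The score was computed and scaled within each set. It does not show whether those libraries cover the stage of the ceh-37 animals, so stage is not decided by this comparison. A deletion of the block in this strain stays open, because the 10 counts left over 13 genes could come from paralogs, and its far edge is not resolved. The nearest gene there, thn-4, had 0 counts in ceh-37 but also in clec-27 and clec-35, which express the block, and srw-23 beyond it had 21 counts in ceh-37 and was not lower among controls (log2 4.29, adjusted p = 0.107). It would not account for the 17 lectins elsewhere that were at least 8-fold lower. Loss of activation by CEH-37 and a difference in genetic background are hypotheses that were not tested here.

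The third pattern is the large number of calls with extract in N2 and clec-35 of set 2. In N2 of set 2 766 calls were left with the score in the model. The score was built from sperm, yolk, oocyte and collagen genes, many of them among the calls. The N2 controls at 0.41 and 0.70 lay apart from the extract libraries (-1.48 to -1.39), so this drop does not separate stage from treatment. The remaining N2 control library had the score of the treated animals without their core response. In clec-35 control and extract libraries did not overlap in score, so the 1445 calls left do not separate stage from treatment, and the explanations cannot be told apart. A slowing of N2 by the extract in every set is argued against by set 1, where the median log2 change of sperm genes was -0.077.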

How the results depend on the processing

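The stage score, the omission of N2 control replicate 3 with ceh-37 extract replicate 2, and the derived counts were added after seeing the data, and the other alternatives were planned. Results that moved are listed by setting, and the cause was not tested.

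With the stage score calls were 144 in N2 set 1, 1 in ceh-37, 766 in N2 set 2, 302 in clec-27, 1445 in clec-35, 461 in clec-35 against clec-27, 1531 and 3209 in the clec-27 and clec-35 controls, and 5 core genes rose in clec-35. Of 17413 values of single genes over all alternatives, 15642 kept their side of the threshold and, where called, their direction. A change of sign in values uncalled in both fits was not counted. A call was lost in 1428 and gained in 330, and 13 with a call in either fit reversed, all with the stage score. These were, in N2 of set 2, mex-5 (0.0864), puf-5 (0.33), rpl-11.1 (0.0624), rpl-42 (0.69) and Y62H9A.5 (1.15). In clec-35 they were chil-14 (0.45, and 0.27 against clec-27), F54D10.7 (2.18), K07A1.6 (1.62), pals-25 (-0.16), ins-5 (-0.0214), vab-3 (-0.0624) and vit-6 (0.47). Without both set 1 libraries calls were 180 in N2, 1 in ceh-37, 90 for ceh-37 against N2 and 6771 among controls (3163 higher, 3608 lower). DESeq2 gave 3 in ceh-37, 109 for ceh-37 against N2 (80 core genes lower), 397 in clec-27, 1897 for clec-27 against N2 (67.1% positive, 17.4% by edgeR), 1665 in clec-27 controls, 2171 between sets (34.7% positive, 63.7% by edgeR), and 77 rising and 35 falling in all 3 strains. With only the compared groups fitted, they were 5233 in ceh-37 controls, 1587 in N2 set 2, 45 in clec-27, 5 in clec-27 controls, and 22 and 8 in all 3 strains. An estimated correlation left 17 of 133 list calls. At adjusted p below 0.01 the control overlap was 48, not 552. Without genes within 1 Mb the chromosome V share of clec-27 reversed, at 19.5%.

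Leaving out 1 library gave ranges of 70 to 204 calls in N2 set 1, 0 to 1 in ceh-37, 37 to 91 for ceh-37 against N2, 2130 to 3669 in ceh-37 controls, 1670 to 6047 in N2 set 2, 55 to 223 in clec-27, 166 to 3344 for clec-27 against N2, 91 to 3286 in clec-27 controls, 7968 to 8412 in clec-35, 2989 to 4039 for clec-35 against N2, 3959 to 6976 for clec-35 against clec-27, 5860 to 7812 in clec-35 controls and 125 to 4200 between sets. The core numbered 68 to 97, with 36 to 60 lower in ceh-37, 62 to 79 in clec-27 and 70 to 78 in clec-35, where 10 to 15 rose. Genes common to the 3 strains numbered 31 to 51 and 10 to 28. Lists from the other set differed by -0.45 to -0.34 in ceh-37, -6.59 to -6.24 in clec-27 and -6.75 to -6.08 in clec-35. With no minimum fold the medians were -0.11, -6.44 and -6.26, and with the list from N2 of the own set -4.53, -1.39 and -1.40. For clec-35 against clec-27 upward calls ranged from 1352 to 3285 and downward from 2607 to 3691 with 1 library left out, downward the larger in all 12, as with DESeq2 size factors in edgeR (2660 and 3311) and no filter (2008 and 3363).

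Replicate numbers did not pair the samples in general. The own number was the best match in 5 of 18 same-number pairs of set 1 and 11 of 45 of set 2. In the N2 and clec-27 controls all 3 same-number pairs deviated together, but N2 control replicate 2 matched clec-27 control replicate 3 best. There the replicate block gave 603 calls against 730 and changed no call of a gene printed for that comparison. With a replicate block 42 and 20 genes were common to the 3 strains. The gene lists were not tested with the block. The other scalings, the filter and the length offset kept these counts within 1.5-fold. Genes with few counts, clec-27 and clec-35 among them, are limited by depth.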

Other observations

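The observations and tests in this part were all chosen only after the values were seen.

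Transcripts of the mitochondrial genome were low in untreated clec-35 animals. All 12 genes tested in set 2 were lower than in N2 controls (median log2 -2.06, from -4.03 to -1.71) and all 12 rose with extract in clec-35 (median 1.94, from 1.59 to 3.93). They made up 0.338 ± 0.153% of the counts in clec-35 controls (SD, n = 3), 1.35 ± 0.125% in N2 controls and 1.18 ± 0.206% in clec-35 with extract. By edgeR 0 of the 12 passed in the responses of N2 and clec-27 or among clec-27 controls.

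Untreated clec-27 animals carried chil-26 at 1126 counts over 3 libraries, and at 13.9 ± 1.03 CPM with extract, without its neighbour chil-27 (4 counts over 3 controls). In N2 of set 2 the extract took chil-26 from 0.0735 ± 0.0731 to 25.04 ± 1.42 CPM, and in clec-35 it was at 14 and 0 counts. Of 15954 genes with at least 26 counts in N2, 59 had 0 counts in all 6 ceh-37 libraries, 1 of them from the core. Among them were 18 of the 161 lectins (Fisher's exact p = 2.0e-22), 8 of 148 outside the block (Fisher's exact p = 1.5e-08). The first test includes the block, which was picked for its silence, and neighbouring lectins are not independent. Both p-values are therefore too small.

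For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real value and the highest of the other splits were 94 and 0 in N2 set 1, 0 and 0 in ceh-37, 3337 and 0 in ceh-37 controls, 4487 and 1727 in N2 set 2, 139 and 0 in clec-27, 9468 and 0 in clec-35, 730 and 1079 in clec-27 controls, and 7640 and 0 in clec-35 controls. In the N2 and clec-27 controls same-numbered libraries deviated together (correlations of 0.171 to 0.465), though N2 control replicate 2 matched clec-27 control replicate 3 best. There 4 splits part every same-numbered pair, the real one with 730 calls and the others with 0 at most. The 1079 came from a split that kept a pair together. As this pairing was recognised after the calls were seen, it does not set the 1079 aside. As many as the real number came from 10 of the 10 splits in ceh-37, 2 in clec-27 controls and 1 in the others.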
